A study of Mus musculus with 12 samples.

How the data were processed

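RNA was measured in CD45-positive cells from the livers of C57BL/6 mice. CD45 is a surface protein of nearly all immune cells, and the cells were captured with a PE-coupled CD45 antibody and magnetic PE beads. Plasmids for human c-Myc and N-ras had been delivered to the liver by hydrodynamic injection on day 0, a method in which a large volume given quickly into a vein carries DNA into hepatocytes. Libraries were made with a stranded mRNA kit and sequenced on an Illumina HiSeq instrument. There were 12 libraries, 3 in each of 4 groups, named control, polyIC, antiPDL1 and combination. The labels do not say whether the 3 replicates of a group came from separate mice, and their numbers were not used as pairs.

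The deposited table gives 1 value per gene and library. The unit was taken to be FPKM (fragment counts scaled by transcript length and by the mapped fragments of the library), which the authors made with Cuffdiff on the mouse genome mm9 according to the submitters' processing notes. That unit rests on the values themselves, since the table does not name it: they are decimals, the library totals differ, and low values of a gene differ between libraries by whole multiples of a single-read step. The Cuffdiff version, the aligner, the gene annotation and the scaling between libraries are not given in the sources used here. Genes are identified by symbol, and no positions are printed because the annotation at hand is of another genome build.

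The table had 24319 entries, of which 23525 matched current mouse symbols, 684 matched older ones and 110 matched none. Values were 0 in every library for 5460 entries. In 27 entries a spreadsheet had turned the symbol into a date, and these were left under that name. For 9 genes (among them Actb, Apoe, Cd5l, Cd74, Ctsb, Fdft1, Psap and Tmsb4x) whole groups were listed at 0 although every library of another group reached at least 5 FPKM, which was read as a failed estimate, and they were left out. The small RNA genes Mir5107, Mir760 and Mir7082 were also listed at 0 in whole groups, and were kept because the rule did not cover small RNA genes. Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested, 11991 in all.

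Read counts are not in the table, so the depth is known only in relative terms. For each pair of libraries the most frequent ratio between low values was taken, over 809 genes. A least squares fit to 65 of the 66 pairs gave relative depths from 0.486 to 1. Group means were 0.792 in control, 0.566 in polyIC, 0.590 in antiPDL1 and 0.817 in combination. The precision of each value was therefore taken from the spread between replicates, and no counting interval or lower limit was computed.

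Differences between groups were tested with limma 3.58.1 (limma-trend, moderated two-sided tests) in R 4.3.3 on log2(FPKM + 1), in 1 fit over all 12 libraries with group as the only term. The Benjamini-Hochberg adjusted p had to be under 0.05. Each treated group was compared with control, the combination with each single treatment, and an interaction contrast asked whether the effect of polyIC differed with and without the antibody. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and statmod 1.5.0 was loaded with limma. In the alternative with a replicate block, the replicate number was a fixed term of the fit.

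Gene lists for immune cell types, other liver cells and pathways, a panel of 15 single genes and the rule for the genes named in the text were written before the data were examined. Lists with at least 5 tested members, 27 in all, were tested with camera, which asks whether a list's genes moved more than other genes, at a preset correlation between genes of 0.01. The same test with an estimated correlation, and fry, which tests a list without comparing it with other genes, were run as alternatives. The cholangiocyte list and the platelet and megakaryocyte list had fewer than 5 tested members and were not tested. For each comparison the rule named the 8 largest rises and 8 largest falls among genes that passed and whose groups did not overlap, leaving out predicted genes, small RNAs and receptor segments. It also named up to 3 members of each list that passed, up to 2 of other cell type or pathway lists, and the panel. For the largest rises and falls, separation of the groups in 3 of 3 libraries was a condition of the choice and is no added support. Panel genes were also compared by two-sided exact permutation tests, for which 3 against 3 libraries cannot give a p under 0.1.

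The alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, quantile normalization, median-of-ratios rescaling, fits of only the groups compared, a replicate block, array quality weights and leaving out each library in turn. Alternatives chosen after the data were seen kept the failed estimates, left out small RNA genes, left out control replicate 2 and antiPDL1 replicate 2 together, or used the mean of the hepatocyte markers as a covariate. The procedure was tested on simulated data with 200 changed genes in each of 5 draws. In the combination against control it recovered 49.2% of 2-fold and 88.8% of 4-fold changes with a mean of 5 false calls, and for the interaction 24.2% and 74.2%. Simulated genes were drawn independently, each with the same spread in all groups, and no library deviated as a whole. The figures are therefore not error rates of the real comparisons.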

Results

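Liver immune cells were profiled in 4 groups of mice that carried human c-Myc and N-ras, a pair of oncogenes, in their hepatocytes. Mice of the polyIC group received 4 mg/kg of polyIC, a synthetic double-stranded RNA sensed by TLR3 and MDA5, on days 14, 16, 18, 20 and 22, together with control IgG. The antiPDL1 group received PBS and 200 µg of an antibody to PD-L1, the ligand of the T cell inhibitory receptor PD-1, on days 17, 19 and 21. Combination mice received both agents, and control mice received PBS and 200 µg of IgG. The treatment protocol puts euthanasia on day 24, while the time point label reads day 22. FPKM totals ran from 476111 to 677535 per library, and Mir6236, a small RNA gene that overlaps ribosomal RNA sequence, took 4.97% to 20.6% of each total.

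In a principal component analysis, component 1 carried 44.0% of the variance, component 2 13.6% and component 3 8.63%. The 3 combination libraries lay together on component 1, from 41.3 to 55.3, and the controls lay at -69.0, -49.6 and -23.1. Within groups the library correlations across genes ran from 0.913 to 0.967, and genes are not independent replicates. By this measure 3 libraries were closer to another group than to their own. The third antiPDL1 library, replicate 2, correlated at 0.950 with controls and 0.927 with its own group, and control replicate 2 correlated at 0.921 with its own group, 0.930 with antiPDL1 and 0.932 with polyIC. The library antiPDL1 replicate 0 correlated at 0.960 with the combination, 0.942 with polyIC and 0.940 with its own group, and its Gzmk and Pdcd1 values were 329 and 153 FPKM, against 32.3 and 13.2 in replicate 1 and 40.6 and 15.7 in replicate 2.

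**Figure D1:**
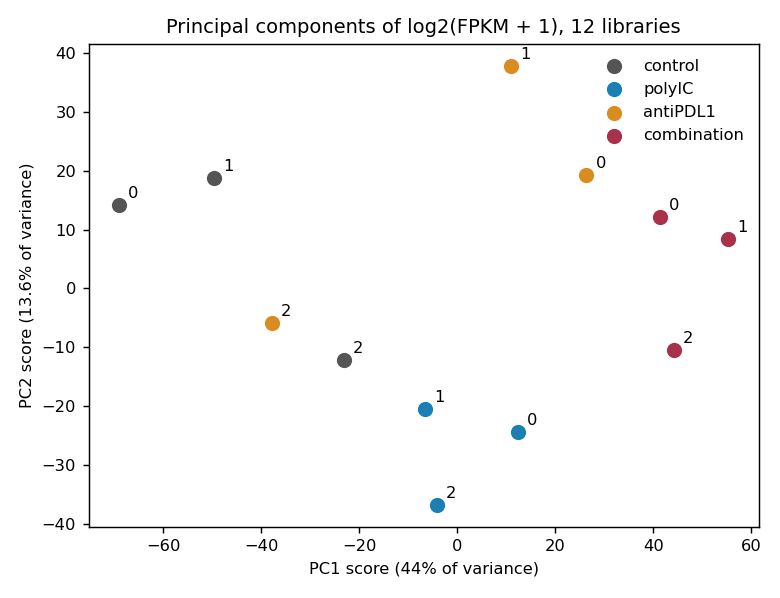
Principal component scores of the 12 libraries on log2(FPKM + 1), component 1 (44.0% of the variance) on the x axis and component 2 (13.6%) on the y axis, with 1 point per library coloured by group and marked with its replicate number. The combination libraries lie from 41.3 to 55.3 on component 1, while antiPDL1 replicate 2 lies at -37.8, among the controls.

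The first comparison asks what polyIC alone did to liver immune cells. Genes of cytotoxic lymphocytes rose. The granzyme gene Gzma, a protease of killer cell granules, went from 196 ± 122 FPKM in control to 2404 ± 671 with polyIC (SD, n = 3 each), and Gzmk from 10.2 ± 6.54 to 214 ± 49.1. Pdcd1, which encodes PD-1, went from 5.35 ± 2.68 to 122 ± 65.6. The genes that fell included Sprr1a, a small proline-rich protein gene of the cornified envelope, from 25.5 ± 16.2 to 0.173 ± 0.0647. They also included the chemokine genes Cxcl13 (37.5 ± 20.4 to 2.80 ± 1.92) and Ccl22 (33.8 ± 10.6 to 3.64 ± 2.35). Each of these genes differed in 3 of 3 libraries from every control.

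Among the 24 CD8 T cell and cytotoxic effector genes, 15 rose and 0 fell with polyIC in limma, or 23 when adjusted over the list alone, with a median log2 change of 2.03. In camera the list had adjusted p = 7.23e-20, and adjusted p = 0.276 with an estimated correlation. NK cell markers rose in 11 of 20, or 17 adjusted over the list alone, with a median of 1.79. As a list they had adjusted p = 5.4e-13, and adjusted p = 0.276 with an estimated correlation. They included Klra7 and Klra8, inhibitory and activating receptors of the Ly49 family, at log2 changes of 2.77 and 2.73. T cell markers rose in 6 of 24, or 17 adjusted over the list alone, with a median of 1.22. Together these genes had adjusted p = 1.18e-08, and adjusted p = 0.354 with an estimated correlation. Checkpoint genes rose in 9 of 18, or 13 adjusted over the list alone, with Tigit at 3.47 and the exhaustion factor gene Tox at 3.22. Camera gave this list adjusted p = 1.04e-08, and adjusted p = 0.306 with an estimated correlation. Of 11 regulatory T cell genes 4 rose, or 7 with 1 lower when adjusted over the list alone, among them Foxp3, the factor that defines these cells, at 1.75. Tested as a list, they had adjusted p = 0.00107, and adjusted p = 0.306 with an estimated correlation. Cell cycle genes rose in 10 of 28, or 23 adjusted over the list alone, such as Kif11 at 1.77. By camera these genes had adjusted p = 1.67e-15, and adjusted p = 0.354 with an estimated correlation.

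Neutrophil markers also rose with polyIC, 7 of 22, and 7 with 1 lower when adjusted over the list alone, led by the granule protein genes Ngp at 4.36, Camp at 4.35 and Ltf at 3.84. The whole list had adjusted p = 0.000155, and adjusted p = 0.361 with an estimated correlation. Monocyte markers rose in 4 of 17, or 5 adjusted over the list alone, with Chil3 at 2.95 and Cx3cr1, the fractalkine receptor, at 1.48. The camera test gave adjusted p = 0.000476, and adjusted p = 0.354 with an estimated correlation. Conventional dendritic cell markers fell in 4 of 17, or 8 adjusted over the list alone, including the lectin gene Mgl2 (10.6 ± 2.13 to 0.656 ± 0.282 FPKM) and Fscn1 at -1.56. Together these genes had adjusted p = 1.2e-06, and adjusted p = 0.306 with an estimated correlation. B cell markers had a median of -0.97 with 0 of 17 past the threshold over all genes and 10 lower when adjusted over the list alone. In camera the list had adjusted p = 1.88e-06, and adjusted p = 0.361 with an estimated correlation. MHC class II, Kupffer cell, plasmacytoid dendritic cell and sinusoidal endothelial lists were lower, at medians of -0.43, -1.04, -0.55 and -0.80, with 0 single genes past the threshold over all genes or over the list alone (camera adjusted p = 0.0105, 0.000462, 0.00302 and 0.00304; with an estimated correlation, adjusted p = 0.361, 0.51, 0.354 and 0.558). Fetal liver and hepatic tumour genes were lower at a median of -0.85 (adjusted p = 0.00895; adjusted p = 0.306 with an estimated correlation), with the epithelial keratin genes Krt18 at -2.30 and Krt8 at -2.05 passing, and 1 higher and 2 lower of 10 when adjusted over the list alone. Ribosomal protein genes were higher at a median of 0.47 with 0 genes passing singly over all genes or over the list alone. As a list they had adjusted p = 2.75e-05, and adjusted p = 0.51 with an estimated correlation. Of these medians 5 moved by over 1.5 times with 1 library out. Without control replicate 0 the neutrophil, endothelial and ribosomal medians were 0.48, -0.26 and 0.25. The Kupffer median was -0.67 without control replicate 1. Without control replicate 2 the neutrophil, endothelial, Kupffer and B cell medians were 1.14, -1.23, -1.68 and -0.59.

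Interferon-stimulated genes did not pass with polyIC, with a median of -0.03 and a mean of 0.02 that differ in sign (adjusted p = 0.935). Panel values were 93.8 ± 17.5 FPKM for Isg15 against 70.1 ± 15.5 in control (log2 0.42, adjusted p = 0.728) and 19.8 ± 0.635 for Ifit1 against 11.7 ± 1.51 (log2 0.72, adjusted p = 0.274), both from limma. Inflammatory cytokines (median -0.16, mean 0.08) and stellate cell markers (median 0.03, mean -0.16) did not pass, and their signs differ. Hepatocyte markers, which report liver RNA carried along with the immune cells, did not pass either (median -0.19, adjusted p = 0.468), and the albumin gene Alb was 851 ± 184 against 1137 ± 574 FPKM. Cd8a, the CD8 coreceptor gene, rose by log2 3.01, while Cd4 stood at 39.0 ± 1.80 against 43.4 ± 17.9 FPKM (adjusted p = 0.903). Outside the lists that passed, Ccl8 rose by 3.19 and the carbonic anhydrase gene Car2 by 2.51.

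In total limma called 437 genes in polyIC against control, 296 higher and 141 lower, with 2660 at an unadjusted p under 0.05, 1314 higher and 1346 lower. Camera called 16 of 27 lists, 9 higher and 7 lower, fry called 7, and camera with an estimated correlation called 0, with 3 at an unadjusted p under 0.05. The gene count became 80, 44 and 1844 without control replicates 0, 1 and 2, the last with 685 higher and 1159 lower. It was 40, 166 and 109 without polyIC replicates 0, 1 and 2. It was 904 without antiPDL1 replicate 2, 268 and 285 without combination replicates 1 and 2, and 2801 (1217 higher, 1584 lower) without control replicate 2 and antiPDL1 replicate 2 together. Array quality weights gave 1617 higher and 1822 lower, so the balance of directions depends on the libraries and their weights. Of 44 named calls 6 held in every such run with 1 library out (Car2, Gzma, Krt18, Krt8, Mgl2 and Sprr1a), and all 44 kept their sign. The fetal liver and plasmacytoid lists missed the threshold without control replicate 2 (adjusted p = 0.0597 and 0.105), the latter also with antiPDL1 replicate 2 out as well (0.0827), as did the endothelial list without control replicate 0 (adjusted p = 0.199).

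**Figure D2:**
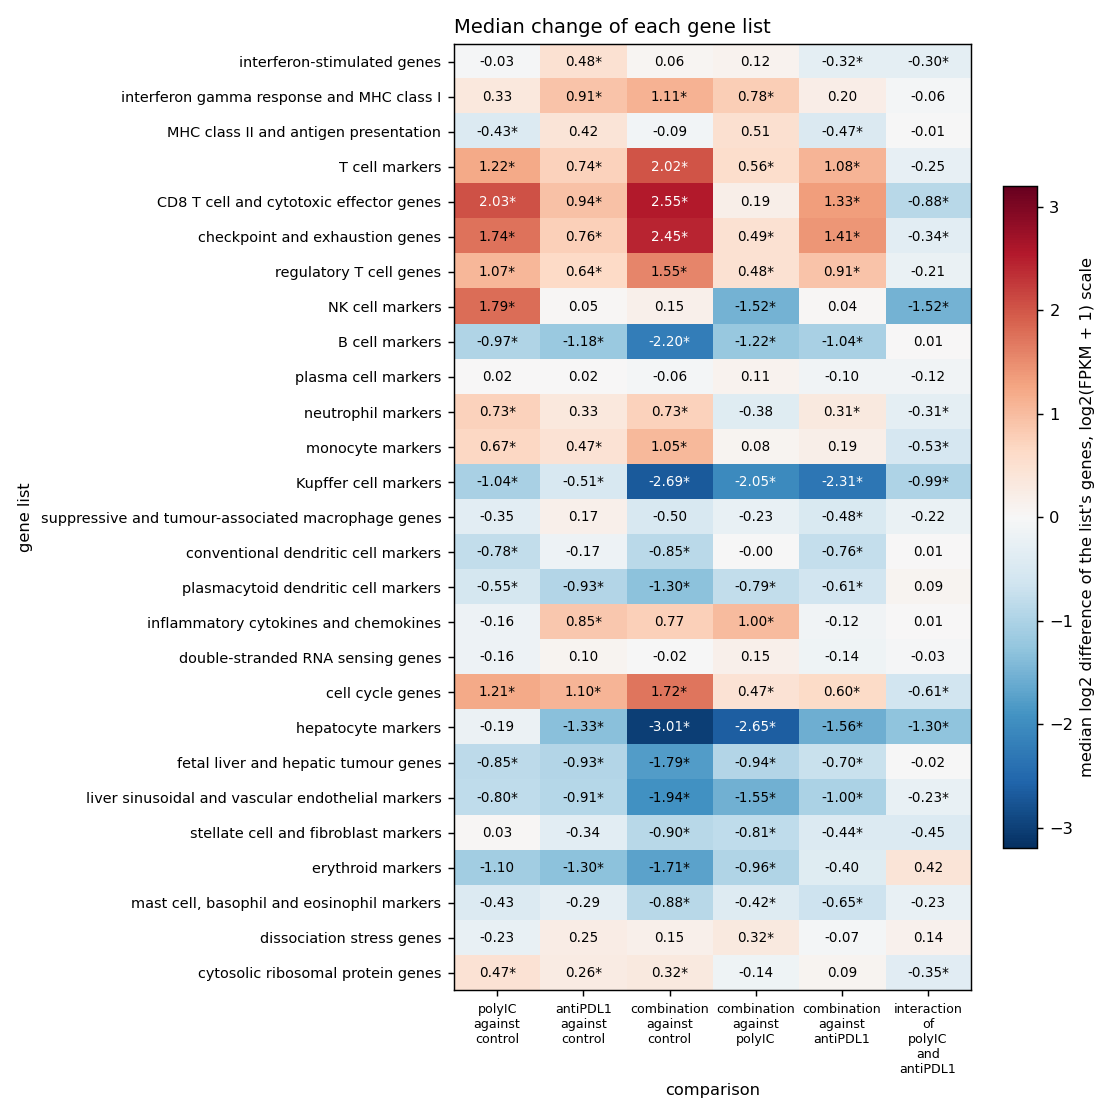
Median log2 difference, on the log2(FPKM + 1) scale, of the tested genes of 27 lists (y axis) in 6 comparisons (x axis), with colour and printed number giving the median. An asterisk marks a camera adjusted p under 0.05 at the preset correlation, and with an estimated correlation 0 lists passed. The cytotoxic list stood at 2.03 with polyIC and 2.55 with the combination.

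Blocking PD-L1 alone was compared with control to ask what the antibody did without polyIC. Keratin and liver genes were among those that fell. Krt18 went from 32.0 ± 14.0 FPKM in control to 4.25 ± 1.90 with antiPDL1 (SD, n = 3 each). Igfbp1, a liver-secreted binding protein of insulin-like growth factors, went from 84.4 ± 36.4 to 7.25 ± 6.29, and Sprr1a from 25.5 ± 16.2 to 0.726 ± 0.399. The tetraspanin genes Tspan8 and Tm4sf4, expressed in epithelia, fell by 3.11 and 3.30 on the log2 scale. Each was lower in 3 of 3 libraries than in every control. Rises did not pass for any gene: 0 in limma, against 913 higher at an unadjusted p under 0.05.

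At the level of lists, cytotoxic effector genes were higher at a median of 0.94 with 0 of 24 passing over all genes and 8 adjusted over the list alone. Camera gave this list adjusted p = 8e-10, and adjusted p = 0.291 with an estimated correlation. Interferon gamma response and MHC class I genes were higher at 0.91, with 13 of 30 adjusted over the list alone. Tested as a list, they had adjusted p = 2.36e-11, and adjusted p = 0.372 with an estimated correlation. Interferon-stimulated genes were higher at 0.48, with 0 of 34 adjusted over the list alone. By camera these genes had adjusted p = 2.04e-05, and adjusted p = 0.526 with an estimated correlation. Cell cycle genes were higher at 1.10, with 22 of 28 adjusted over the list alone. The whole list had adjusted p = 1.16e-16, and adjusted p = 0.291 with an estimated correlation. Checkpoint genes (0.76), regulatory T cell genes (0.64) and T cell markers (0.74) were higher, with 7, 2 and 0 genes adjusted over the list alone (adjusted p = 1.73e-06, 0.000782 and 0.000101; with an estimated correlation, adjusted p = 0.291, 0.291 and 0.504). Monocyte markers (0.47), inflammatory cytokines (0.85) and ribosomal protein genes (0.26) were higher with 0 genes adjusted over the list alone (adjusted p = 0.00206, 0.000231 and 0.00274; with an estimated correlation, adjusted p = 0.379, 0.379 and 0.631). Leaving out 1 library moved 9 of these medians by over 1.5 times. Without control replicate 0 the T cell and ribosomal medians were 0.46 and 0.032. Without control replicate 2 the interferon-stimulated, monocyte and ribosomal medians were 0.21, 0.74 and 0.45. Without antiPDL1 replicate 0 the cytotoxic, checkpoint, regulatory T cell, T cell, cytokine and ribosomal medians were 0.57, 0.41, 0.42, 0.44, 0.32 and 0.11. Without antiPDL1 replicate 1 the interferon-stimulated, interferon gamma and ribosomal medians were 0.13, 0.52 and 0.12. Without antiPDL1 replicate 2 the interferon-stimulated, interferon gamma, monocyte, cytokine and ribosomal medians were 0.83, 1.43, 0.89, 1.36 and 0.51.

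B cell markers were lower at -1.18, with 15 of 17 adjusted over the list alone. The camera test gave adjusted p = 3.75e-10, and adjusted p = 0.291 with an estimated correlation. Plasmacytoid dendritic cell markers were lower at -0.93 with 8 of 14. Together these genes had adjusted p = 0.000101, and adjusted p = 0.291 with an estimated correlation. Hepatocyte markers were lower at -1.33, with 8 of 28 adjusted over the list alone. In camera the list had adjusted p = 9e-09, and adjusted p = 0.379 with an estimated correlation. Fetal liver genes (-0.93), erythroid markers (-1.30), endothelial markers (-0.91) and Kupffer cell markers (-0.51) were lower, with 4, 4, 0 and 0 genes adjusted over the list alone (adjusted p = 8.9e-06, 0.00159, 0.000106 and 0.0487; with an estimated correlation, adjusted p = 0.203, 0.291, 0.504 and 0.667). Leaving out 1 library moved 5 of these medians by over 1.5 times. The Kupffer median was -0.24, -0.16 and -1.16 without control replicates 0, 1 and 2, and -0.12 and -0.97 without antiPDL1 replicates 0 and 2. The endothelial median was -0.42 and -1.42 without control replicates 0 and 2, and the plasmacytoid median -0.58 without control replicate 2. Hepatocyte and fetal liver medians were -0.81 without antiPDL1 replicate 1 and -1.42 without antiPDL1 replicate 2, respectively. NK cell markers did not pass (median 0.05, adjusted p = 0.323), nor did plasma cell markers, whose median of 0.02 and mean of -0.06 differ in sign. Cd274, which encodes PD-L1 itself, was 46.3 ± 22.5 against 19.3 ± 4.20 FPKM (log2 1.09, adjusted p = 0.211), and Gzmb 318 ± 214 against 63.8 ± 28.8 (log2 2.10, adjusted p = 0.156), both short of the limma threshold.

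Limma called 25 genes in antiPDL1 against control, 0 higher and 25 lower, with 2034 at an unadjusted p under 0.05. Quantile normalization gave 4 higher and 17 lower, median-of-ratios rescaling 4 and 26. Camera called 17 of 27 lists, 10 higher and 7 lower, fry 1, and camera with an estimated correlation 0, with 2 at an unadjusted p under 0.05. The count became 0 without control replicate 1 (limma) and 306 without control replicate 2. It was 14 without polyIC replicate 2. Without antiPDL1 replicates 0, 1 and 2 it was 1, 1 and 2089, the last with 1429 higher and 660 lower. It was 15, 14 and 13 without combination replicates 0, 1 and 2, and 3285 (1720 higher, 1565 lower) without control replicate 2 and antiPDL1 replicate 2 together. Of 10 named calls 0 held in every run with 1 library out and all kept their sign. The Kupffer list missed the threshold without control replicates 0 and 1, polyIC replicates 1 and 2, antiPDL1 replicate 0 or combination replicates 0 and 2 (adjusted p = 0.357, 0.443, 0.0509, 0.0524, 0.972, 0.0515 and 0.0583) and under median-of-ratios rescaling (0.0924). So did the erythroid list without control replicate 2 (0.0579), and the ribosomal list without control replicate 0 (0.557) or after quantile normalization (0.200).

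The combination was compared with control to ask what both agents did together. Cytotoxic T cell genes stood at high levels: Gzmk reached 526 ± 88.2 FPKM against 10.2 ± 6.54 in control (SD, n = 3 each), Gzmb 1162 ± 378 against 63.8 ± 28.8, and Ifng, the interferon gamma gene, 123 ± 35.9 against 12.97 ± 4.17. Receptors that restrain T cells rose with them, Pdcd1 to 219 ± 41.6 from 5.35 ± 2.68 and Ctla4 to 97.0 ± 36.7 from 2.87 ± 1.31. Genes of resident liver macrophages (Kupffer cells) fell, the lectin Clec4f from 2408 ± 1595 to 23.2 ± 17.2 and the complement receptor Vsig4 from 1074 ± 605 to 19.4 ± 11.2. Alb fell from 1137 ± 574 to 114 ± 33.7. Each of these genes differed in 3 of 3 combination libraries from every control.

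**Figure D3:**
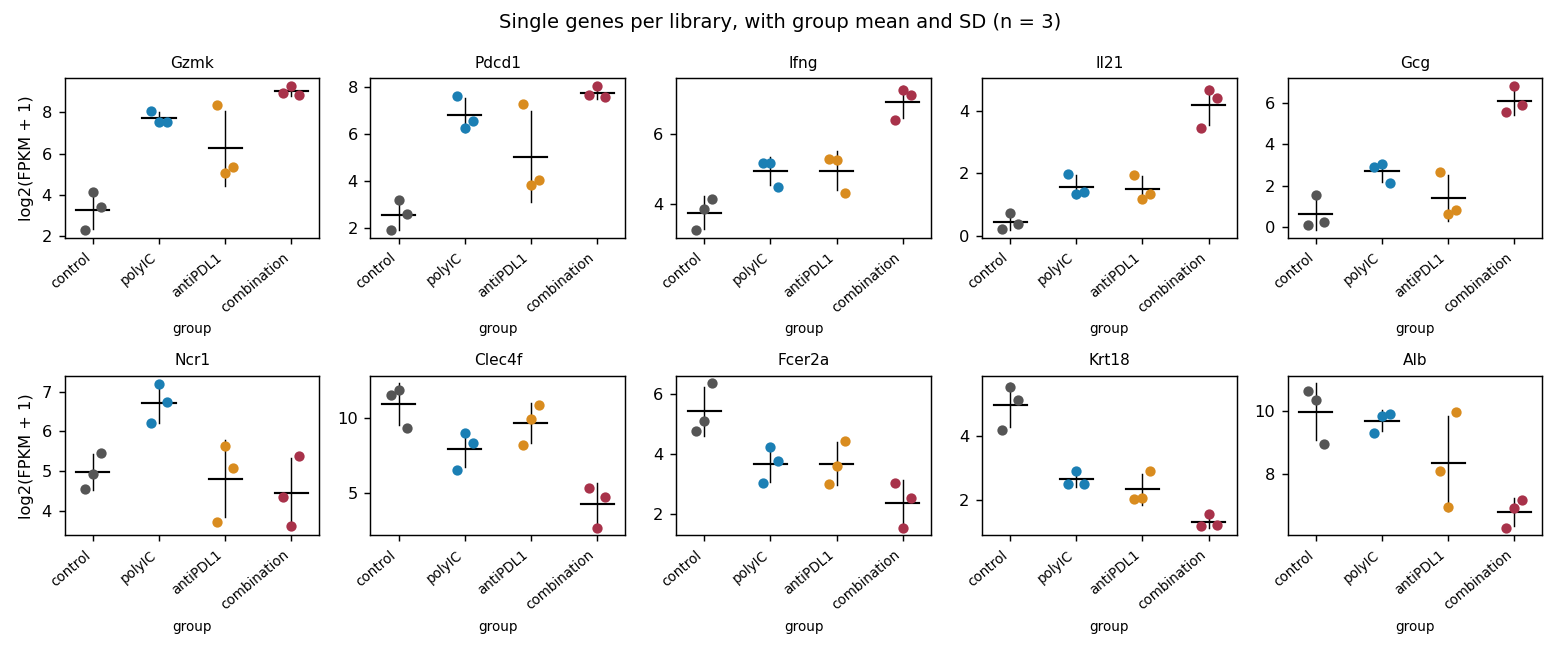
Values on the log2(FPKM + 1) scale (y axis) of 10 genes in each library by group (x axis), with 1 point per library, a horizontal line at the group mean and a vertical line of 1 SD to each side. Group means of Gzmk, Pdcd1, Ifng, Il21 and Gcg are highest in the combination, where Gzmk averages 526 FPKM, and those of Clec4f, Fcer2a, Krt18 and Alb are lowest there.

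Of the 24 cytotoxic effector genes 19 rose and 0 fell, or 21 adjusted over the list alone, with a median of 2.55. As a list they had adjusted p = 1e-11, and adjusted p = 0.278 with an estimated correlation. T cell markers rose in 19 of 24 with 1 lower, the same counts adjusted over the list alone, with Cd27 at 2.79 and Cd247, the CD3 zeta chain gene, at 2.49. Camera gave this list adjusted p = 3.1e-07, and adjusted p = 0.331 with an estimated correlation. Checkpoint genes rose in 13 of 18, or 14 adjusted over the list alone, with Tigit at 4.47. Tested as a list, they had adjusted p = 1.01e-07, and adjusted p = 0.278 with an estimated correlation. Regulatory T cell genes rose in 7 of 11 with 1 lower, the same counts adjusted over the list alone: Tnfrsf4, which encodes OX40, at 3.77, the chemokine receptor gene Ccr8 at 3.19 and Foxp3 at 1.90. By camera these genes had adjusted p = 0.00157, and adjusted p = 0.278 with an estimated correlation. Both coreceptor genes rose, Cd8a by 3.18 and Cd4 by 1.24. Interferon gamma response genes rose in 16 of 30, or 21 adjusted over the list alone, with Gbp2 at 2.25 and Cxcl9, a chemokine that attracts T cells, at 2.17. The whole list had adjusted p = 7.39e-07, and adjusted p = 0.388 with an estimated correlation. Cell cycle genes rose in 25 of 28, or 27 adjusted over the list alone, with a median of 1.72. In camera the list had adjusted p = 6.6e-13, and adjusted p = 0.278 with an estimated correlation. Monocyte and neutrophil markers rose in 8 of 17 and 7 of 22, the same counts adjusted over the list alone, with Chil3 at 2.82 and Clec4e at 2.59 (list adjusted p = 0.0133 and 0.0247; with an estimated correlation, adjusted p = 0.388 and 0.572). Of 26 ribosomal protein genes 2 rose, 0 adjusted over the list alone. The camera test gave adjusted p = 0.0133, and adjusted p = 0.709 with an estimated correlation.

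All 17 B cell markers fell, over all genes and when adjusted over the list alone, at a median of -2.20, with the low-affinity IgE receptor gene Fcer2a at -3.06 and the lineage factor gene Pax5 at -2.58. Together these genes had adjusted p = 1.73e-10, and adjusted p = 0.278 with an estimated correlation. Kupffer cell markers fell in 13 of 18, or 15 adjusted over the list alone, with Cd163, a haemoglobin scavenger receptor gene, at -5.75. In camera the list had adjusted p = 7.28e-08, and adjusted p = 0.278 with an estimated correlation. Hepatocyte markers fell in 23 of 28, or 24 with 1 higher when adjusted over the list alone, at a median of -3.01. As a list they had adjusted p = 1e-11, and adjusted p = 0.278 with an estimated correlation. Endothelial markers fell in 14 of 17, or 15 adjusted over the list alone, such as Cdh5 at -3.52 and Stab2 at -3.33. Camera gave this list adjusted p = 8.09e-08, and adjusted p = 0.278 with an estimated correlation. Conventional and plasmacytoid dendritic cell markers fell in 9 of 17 and 8 of 14, or 9 and 9 adjusted over the list alone, with Cd209a at -2.76 and Siglech at -2.38 (list adjusted p = 8.11e-05 and 7.14e-05; with an estimated correlation, adjusted p = 0.278 for both). Fetal liver genes fell in 7 of 10, the same count adjusted over the list alone, with the imprinted fetal RNA H19 at -3.50. Tested as a list, they had adjusted p = 0.000569, and adjusted p = 0.278 with an estimated correlation. Stellate cell, erythroid and mast cell, basophil and eosinophil markers fell in 2 of 9, 4 of 7 and 3 of 6, or 5, 5 and 4 adjusted over the list alone (list adjusted p = 0.0124, 0.00892 and 0.00626; with an estimated correlation, adjusted p = 0.374, 0.278 and 0.278).

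NK cell markers did not pass (median 0.15, adjusted p = 0.417), although 3 of 20 rose, among them Gzma at 2.66 and Eomes, a factor of NK and CD8 T cells, at 2.79, and Ncr1, the NK receptor NKp46, was 23.9 ± 15.2 against 31.5 ± 10.4 FPKM (adjusted p = 0.468). Interferon-stimulated genes did not pass as a list (median 0.06, adjusted p = 0.736), with Zbp1, a sensor of Z-form nucleic acids, at 1.69 and Isg20 at 1.44 among 3 genes that rose and 1 that fell. Lists of MHC class II (-0.09, adjusted p = 0.418), plasma cells (-0.06, 0.667), suppressive macrophages (-0.50, 0.137), inflammatory cytokines (0.77, 0.237), dissociation stress (0.15, 0.756) and double-stranded RNA sensing (median -0.02 and mean 0.06, which differ in sign, 0.888) did not pass. Within them Il10, an inhibitory cytokine gene, rose by 3.83, Prdm1, the plasma cell and effector T cell factor Blimp-1, rose by 1.81, and the B cell chemokine gene Cxcl13 fell by 4.57.

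Limma called 3527 genes in the combination against control, 29.4% of those tested, 1576 higher and 1951 lower, with 5109 at an unadjusted p under 0.05. The balance of directions was the other way after quantile normalization (2004 higher, 1644 lower), with a mean FPKM of at least 5 (1115, 848), in a fit of only these groups (1654, 1537), with array quality weights (3729, 3154) and without antiPDL1 replicate 2 (2372, 2070). Camera called 19 of 27 lists, 9 higher and 10 lower, fry 17, and camera with an estimated correlation 0, with 1 at an unadjusted p under 0.05. The gene count became 1700 and 2215 without control replicates 0 and 1, 1681 and 2256 without combination replicates 1 and 2, and 2 with the mean of the hepatocyte markers as a covariate. Of 81 named calls 62 held in every run with 1 library out, and all kept their sign in each such run that tested them. The neutrophil list missed the threshold without control replicate 0 or combination replicate 2 (adjusted p = 0.149 and 0.154), the erythroid list without control replicate 2 (0.0665), the ribosomal list without control replicate 0 (0.309), and after quantile normalization the neutrophil, monocyte, stellate and ribosomal lists (0.0733, 0.0545, 0.0713 and 0.122).

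Against polyIC alone, the combination shows what adding the antibody did. Il21, a cytokine gene of helper T cells, rose from 2.04 ± 0.796 FPKM to 18.0 ± 7.32 (SD, n = 3 each), Il10 from 6.87 ± 1.69 to 50.9 ± 25.2 and Ifng from 30.5 ± 7.78 to 123 ± 35.9. Genes of hepatocyte secreted proteins fell, Ttr (transthyretin) from 151 ± 13.3 to 15.3 ± 4.91 and the apolipoprotein Apoc3 from 144 ± 21.1 to 15.8 ± 6.84. Klrc1, the NK receptor NKG2A, fell from 110 ± 12.7 to 35.9 ± 10.1. Each differed in 3 of 3 libraries from every polyIC library.

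NK cell markers were lower at a median of -1.52, with 1 of 20 passing over all genes and 16 adjusted over the list alone. By camera these genes had adjusted p = 1.94e-12, and adjusted p = 0.169 with an estimated correlation. Cytotoxic effector genes did not pass (median 0.19, adjusted p = 0.452) with 1 of 24 higher over all genes and over the list alone. Interferon gamma response genes were higher at 0.78, with 1 of 30 passing and 10 adjusted over the list alone. The whole list had adjusted p = 6.99e-10, and adjusted p = 0.347 with an estimated correlation. Checkpoint genes (0.49), regulatory T cell genes (0.48) and T cell markers (0.56) were higher, with 2, 1 and 0 passing and 2, 2 and 0 adjusted over the list alone, among them Tnfrsf4 at 1.96 (list adjusted p = 0.00371, 0.0159 and 0.00508; with an estimated correlation, adjusted p = 0.505, 0.347 and 0.666). Cell cycle genes (0.47), inflammatory cytokines (1.00) and dissociation stress genes (0.32) were higher, with 0, 0 and 1 passing and 0, 4 and 1 adjusted over the list alone (adjusted p = 4.04e-05, 0.00846 and 0.0279; with an estimated correlation, adjusted p = 0.591, 0.505 and 0.505). The checkpoint median was 0.74 without polyIC replicate 0, and the stress median 0.21 without polyIC replicate 2.

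Hepatocyte markers fell in 14 of 28, or 26 adjusted over the list alone, at a median of -2.65. The camera test gave adjusted p = 2.26e-26, and adjusted p = 0.169 with an estimated correlation. B cell markers were lower at -1.22 with 0 of 17 passing and 14 adjusted over the list alone. Together these genes had adjusted p = 5.86e-11, and adjusted p = 0.314 with an estimated correlation. Kupffer cell markers were lower at -2.05 with 0 of 18 passing and 11 adjusted over the list alone. In camera the list had adjusted p = 2.49e-09, and adjusted p = 0.314 with an estimated correlation. Endothelial markers were lower at -1.55, 2 of 17 passing and 13 adjusted over the list alone, with the lymphatic and sinusoidal receptor gene Lyve1 at -2.50. As a list they had adjusted p = 2.95e-09, and adjusted p = 0.314 with an estimated correlation. Fetal liver (-0.94), plasmacytoid (-0.79), stellate (-0.81), erythroid (-0.96) and mast cell, basophil and eosinophil (-0.42) lists were lower, with 1, 0, 0, 1 and 0 genes passing and 6, 0, 5, 2 and 1 adjusted over the list alone (adjusted p = 0.00015, 0.000295, 0.000675, 0.000489 and 0.00509; with an estimated correlation, adjusted p = 0.169, 0.314, 0.314, 0.169 and 0.315). Within the neutrophil list, which did not pass (adjusted p = 0.105), the primary granule genes Mpo and Elane fell by 1.87 and 1.67. The plasma cell list did not pass, and its median of 0.11 and mean of -0.32 differ in sign (adjusted p = 0.329).

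Limma called 148 genes in the combination against polyIC, 20 higher and 128 lower, with 1624 at an unadjusted p under 0.05. Quantile normalization gave 4 higher and 2 lower, median-of-ratios rescaling 6 and 14, no filter 14 and 12, and array quality weights 1868 and 1786. Camera called 17 of 27 lists, 7 higher and 10 lower, fry 4, and camera with an estimated correlation 0, with 4 at an unadjusted p under 0.05. The gene count became 384, 7 and 536 without control replicates 0, 1 and 2. It was 0, 0 and 1 without polyIC replicates 0, 1 and 2 (limma), and 499 without antiPDL1 replicate 2. It was 4, 4 and 3 without combination replicates 0, 1 and 2, 1116 without control replicate 2 and antiPDL1 replicate 2 together, and 1 with the hepatocyte covariate. Of 24 named calls 0 held in every run with 1 library out and all kept their sign in each such run that tested them. The regulatory T cell and cytokine lists missed the threshold without combination replicate 2 (adjusted p = 0.0996 and 0.142), the stress list without polyIC replicate 0 (0.0667), the regulatory T cell list without control replicate 2 and antiPDL1 replicate 2 together (0.0755), and the T cell, stress and mast cell lists after quantile normalization (0.124, 0.0726 and 0.0931).

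Set against antiPDL1 alone, the combination shows what adding polyIC did. Il21 rose from 1.89 ± 0.866 FPKM to 18.0 ± 7.32 (SD, n = 3 each) and Il10 from 4.28 ± 3.43 to 50.9 ± 25.2. Gcg, the proglucagon gene, rose from 2.22 ± 2.69 to 73.5 ± 36.2. All 3 genes that fell are known from dendritic cells or macrophages. Cd207 (langerin, a lectin of dendritic cells) went from 45.1 ± 20.0 to 2.69 ± 1.37, the T cell chemokine Ccl17 from 11.2 ± 2.24 to 0.876 ± 0.596, and Mgl2 from 5.92 ± 2.86 to 0.629 ± 0.254. Each of these genes differed in 3 of 3 libraries from every antiPDL1 library.

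Cytotoxic effector genes were higher at a median of 1.33, with 0 of 24 passing over all genes and 16 adjusted over the list alone. Camera gave this list adjusted p = 2.09e-12, and adjusted p = 0.236 with an estimated correlation. T cell markers were higher at 1.08, 0 of 24 passing, and 18 higher with 1 lower when adjusted over the list alone. Tested as a list, they had adjusted p = 3.44e-09, and adjusted p = 0.236 with an estimated correlation. Checkpoint (1.41) and regulatory T cell genes (0.91) were higher, with 1 and 0 passing and 12 and 6 adjusted over the list alone (adjusted p = 3.33e-08 and 0.00237; with an estimated correlation, adjusted p = 0.236 for both). Cell cycle genes (0.60) and neutrophil markers (0.31) were higher with 0 genes adjusted over the list alone (adjusted p = 5.88e-08 and 0.0195; with an estimated correlation, adjusted p = 0.408 and 0.54). The neutrophil median was 0.64 and 0.049 without antiPDL1 replicates 1 and 2 and 0.18 without combination replicate 2, and the cell cycle median 0.16 without antiPDL1 replicate 2. NK cell markers did not pass (median 0.04, adjusted p = 0.412).

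Kupffer cell markers were lower at -2.31, with 14 of 18 adjusted over the list alone, and hepatocyte markers at -1.56, with 19 of 28 (adjusted p = 3.9e-14 and 5.36e-13; with an estimated correlation, adjusted p = 0.236 for both). Conventional dendritic cell markers were lower at -0.76, 1 of 17 passing and 8 adjusted over the list alone. By camera these genes had adjusted p = 1.51e-09, and adjusted p = 0.236 with an estimated correlation. B cell (-1.04), endothelial (-1.001), plasmacytoid (-0.61), suppressive macrophage (-0.48) and MHC class II lists (-0.47) were lower, with 2, 5, 1, 6 and 1 genes lower adjusted over the list alone, and 1 suppressive macrophage gene, Il10, higher (adjusted p = 1.01e-08, 3.27e-09, 0.00237, 0.00237 and 0.000371; with an estimated correlation, adjusted p = 0.236 for all). Fetal liver (-0.70), mast cell, basophil and eosinophil (-0.65), stellate (-0.44) and interferon-stimulated lists (-0.32) were also lower, with 3, 1, 0 and 0 genes lower adjusted over the list alone, and 1 fetal liver gene higher (adjusted p = 0.0195, 0.0005, 0.0133 and 0.000135; with an estimated correlation, adjusted p = 0.236, 0.236, 0.38 and 0.54). Leaving out 1 library moved 7 of these medians by over 1.5 times. The suppressive macrophage median was -0.26 and -0.90 without antiPDL1 replicates 0 and 1, and -0.26 without combination replicate 2. Without antiPDL1 replicate 1 the interferon-stimulated, MHC class II, stellate and mast cell medians were -0.073, -0.27, -0.73 and -0.40. Without antiPDL1 replicate 2 the interferon-stimulated, MHC class II, mast cell, plasmacytoid and hepatocyte medians were -0.74, -0.75, -0.41, -0.31 and -0.97. Without combination replicate 1 the MHC class II and plasmacytoid medians were -0.30 and -0.36.

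Limma called 15 genes in the combination against antiPDL1, 12 higher and 3 lower, with 1727 at an unadjusted p under 0.05, 758 higher and 969 lower. The balance of called genes was also the other way with a pseudocount of 0.1 (5 higher, 6 lower), array quality weights (347, 471), and a fit of only these groups (0, 1). Camera called 18 of 27 lists, 6 higher and 12 lower, while fry and camera with an estimated correlation called 0, with 11 and 2 at an unadjusted p under 0.05. The gene count became 9, 9 and 278 without control replicates 0, 1 and 2, the last with 99 higher and 179 lower. It was 8 and 7 without polyIC replicates 0 and 2. Without antiPDL1 replicates 0, 1 and 2 it was 329, 8 and 0 (limma). It was 5, 0 and 1 without combination replicates 0, 1 and 2 (limma), 88 (25 higher, 63 lower) without control replicate 2 and antiPDL1 replicate 2 together, and 3 with the hepatocyte covariate. Of 11 named calls 0 held in every run with 1 library out and all kept their sign. Lists missed the threshold without antiPDL1 replicate 0 (neutrophil, suppressive macrophage and stellate, adjusted p = 0.177, 0.0906 and 0.134), antiPDL1 replicate 1 (interferon-stimulated, 0.150), antiPDL1 replicate 2 (plasmacytoid, fetal liver and stellate, 0.0562, 0.323 and 0.0589), combination replicate 2 (neutrophil, 0.323), control replicate 2 and antiPDL1 replicate 2 together (plasmacytoid and fetal liver, 0.0730 and 0.384) and after quantile normalization (stellate, 0.0724).

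The interaction contrast asks whether the effect of polyIC differed with and without the antibody. NK cell markers stood out: their effect of polyIC was lower with the antibody by a median of -1.52, with 0 of 20 genes passing over all genes and 15 lower adjusted over the list alone. The whole list had adjusted p = 5.8e-24, and adjusted p = 0.0962 with an estimated correlation. Ncr1 was 31.5 ± 10.4 FPKM in control, 108 ± 36.3 with polyIC, 31.1 ± 18.1 with antiPDL1 and 23.9 ± 15.2 with the combination (SD, n = 3 each). Orm2, an acute phase protein gene, was 0.571 ± 0.209, 8.84 ± 2.52, 0.962 ± 0.338 and 1.36 ± 0.307 FPKM in the same order, an interaction of -2.35 (adjusted p = 0.0305, 3 of 3 polyIC libraries above the other 9).

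**Figure D4:**
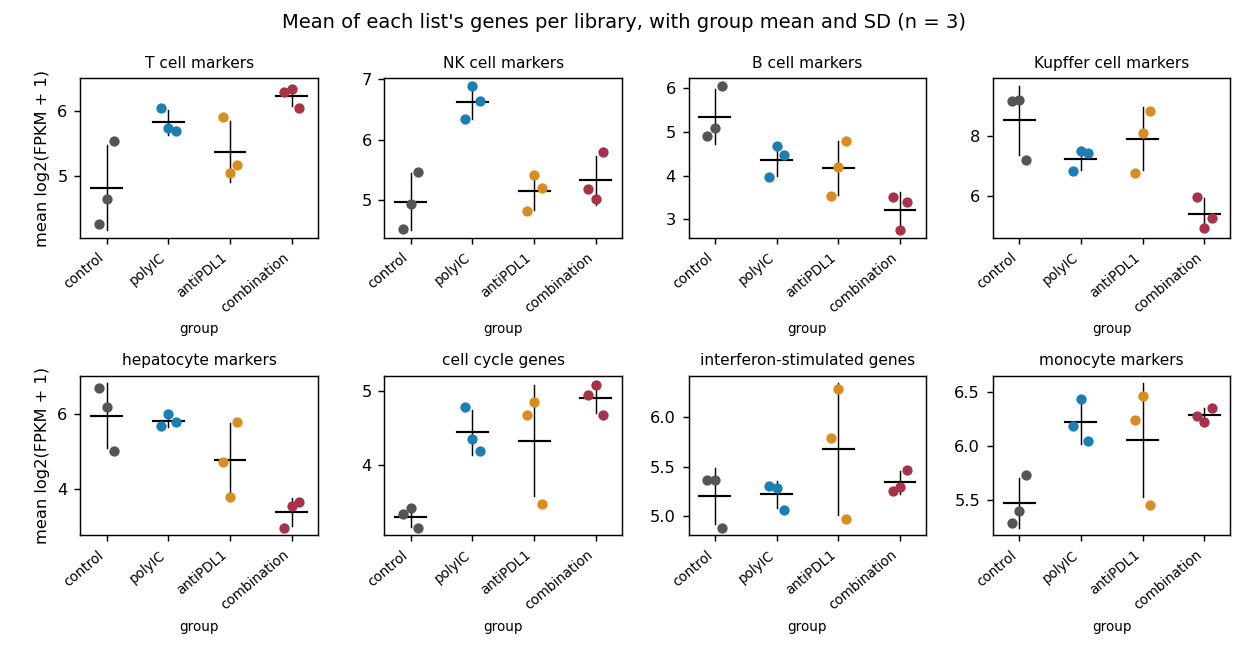
Mean log2(FPKM + 1) of the tested genes of 8 lists (y axis, one panel each) in each library by group (x axis), with 1 point per library, a horizontal line at the group mean and a vertical line of 1 SD to each side. The NK panel is highest in the 3 polyIC libraries, and the means of the hepatocyte and B cell panels are lowest in the combination.

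Cytotoxic effector genes (-0.88), cell cycle genes (-0.61), hepatocyte markers (-1.30) and Kupffer cell markers (-0.99) were lower in the interaction, with 2, 0, 0 and 0 genes adjusted over the list alone (adjusted p = 1.66e-10, 1.66e-10, 3.28e-14 and 8.64e-07; with an estimated correlation, adjusted p = 0.623, 0.705, 0.623 and 0.705). Monocyte (-0.53), neutrophil (-0.31), checkpoint (-0.34), interferon-stimulated (-0.30), ribosomal protein (-0.35) and endothelial lists (-0.23) were also lower, with 2 neutrophil genes and 0 of the others adjusted over the list alone (adjusted p = 0.000256, 0.000289, 0.0376, 1.74e-05, 2.91e-06 and 0.00458; with an estimated correlation, adjusted p = 0.623, 0.705, 0.723, 0.705, 0.705 and 0.723). All 10 of these medians moved by over 1.5 times with 1 library out. For the cytotoxic list the median was -0.55 without control replicate 0 and -0.37 without antiPDL1 replicate 0, and for cell cycle genes -0.36 and -1.035 without antiPDL1 replicates 1 and 2. Without control replicate 2 and without antiPDL1 replicate 2 the hepatocyte median was -0.75 and -0.78, and the Kupffer median -0.34 and -0.53. The monocyte median was -0.32, -0.30, -0.32 and -0.22 without control replicate 0, polyIC replicate 1 and antiPDL1 replicates 0 and 1. The checkpoint median was -0.21 without polyIC replicate 0, 0.026 without antiPDL1 replicate 0 and -0.68 without antiPDL1 replicate 2. The interferon-stimulated median was -0.13 without control replicate 2, and -0.027 and -0.64 without antiPDL1 replicates 1 and 2. Ribosomal protein genes had -0.16 and -0.54 without control replicates 0 and 2, and -0.22, -0.23 and -0.60 without antiPDL1 replicates 0, 1 and 2. The neutrophil median was -0.091 and -0.63 without control replicates 0 and 2, 0.013 without polyIC replicate 1, -0.72, 0.12 and -0.55 without antiPDL1 replicates 0, 1 and 2, and -0.20 without combination replicate 0. Endothelial markers had -0.78 and 0.063 without control replicates 0 and 2, -0.57 and -0.13 without polyIC replicates 0 and 1, -0.70 and -0.090 without antiPDL1 replicates 0 and 2, and -0.60, -0.086 and -0.15 without combination replicates 0, 1 and 2. T cell (-0.25, adjusted p = 0.222) and B cell markers (0.01, 0.924) did not pass. Signs of median and test differ for inflammatory cytokines (0.01), erythroid markers (0.42) and fetal liver genes (-0.02), none of which passed.

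Limma called 3 genes for the interaction, 1 higher and 2 lower, with 293 at an unadjusted p under 0.05. Besides Orm2 these were small RNA genes with a fitted value of no use as a fold: Mir760 was listed at 0 outside the controls, where it was 7.67 ± 3.37 FPKM, and Mir5107 was listed at 0 outside polyIC, where it was 85.7 ± 52.8. Below the threshold, as the rule for comparisons with few calls requires, came Sprr1a (3.54, adjusted p = 0.425), Angptl2 (1.51, 0.569), Mir7082 (listed at 0 in polyIC) and Tgfa (0.90, 0.699) among the higher, and the Ly49 receptor gene Klra19 (-1.84, 0.164), Elane (-1.88, 0.164) and Tnfsf8, the CD30 ligand (-1.59, 0.637), among the lower. In polyIC, antiPDL1 and combination, Sprr1a averaged 0.173, 0.726 and 0.0788 FPKM and Tgfa 0.395, 0.349 and 0.143. At such values a further fall has little room on the log2(FPKM + 1) scale, so their positive interactions show no larger effect of polyIC with the antibody. Camera called 11 of 27 lists, 0 higher and 11 lower, while fry and camera with an estimated correlation called 0, with 1 and 1 at an unadjusted p under 0.05. The gene count became 5, 1 and 1 without control replicates 0, 1 and 2. It was 0, 0 and 1 without polyIC replicates 0, 1 and 2 (limma), 1 without any of the combination replicates 0, 1 and 2, 0 without small RNA genes and 5 without control replicate 2 and antiPDL1 replicate 2 together. Mir5107 passed in the 9 runs with 1 library out that tested it, and failed the expression filter without any 1 of the polyIC replicates 0, 1 and 2. Its zeros in whole groups match those of the genes left out as failed estimates. Orm2 passed in 2 of those 12 runs, without control replicate 0 or polyIC replicate 2, and otherwise had adjusted p from 0.0645 to 0.235. The calls of lists in the interaction were lost for checkpoint genes without control replicates 0 and 1, polyIC replicates 0 and 2, antiPDL1 replicate 0 or combination replicate 1 (adjusted p = 0.437, 0.0870, 0.0903, 0.0921, 0.642 and 0.0927) and under median-of-ratios rescaling (0.0515). They were lost for neutrophil markers without control replicate 0, polyIC replicates 0 and 1 or antiPDL1 replicate 1 (0.183, 0.0956, 0.142 and 0.0911), and for Kupffer markers without control replicate 2 or antiPDL1 replicate 2 (0.0780 and 0.140). They were also lost for endothelial markers without control replicate 2, polyIC replicate 2, antiPDL1 replicate 2 or combination replicate 1 (0.643, 0.0839, 0.689 and 0.152), for interferon-stimulated genes without antiPDL1 replicate 1 (0.256), and for ribosomal protein genes without control replicate 0 (0.118). With control replicate 2 and antiPDL1 replicate 2 both out, the Kupffer, hepatocyte and endothelial calls were lost (0.705, 0.506 and 0.309), with medians of 0.11, -0.30 and 0.29, of which the first and last changed sign.

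The 3 comparisons with control share their controls, which alone makes their changes move together. Simulations of no effect drew each gene independently, so they hold no library that deviates across many genes at once. A correlation above the simulated value is therefore no measure of a shared treatment effect. Changes with polyIC and with the combination correlated across genes at 0.760, against 0.506 in these simulations, and 251 genes were higher and 128 lower in both. For antiPDL1 and the combination the correlation was 0.835 against 0.502, with 25 genes lower in both, and for polyIC and antiPDL1 0.657 against 0.4995, with 23 lower in both. Genes lower in all 3 comparisons numbered 23 and included the epithelial genes Krt8, Krt18, Cldn2, Tspan8 and Tm4sf4 and the growth factor gene Tgfa. Over the 45 exact two-sided permutation tests of the panel, 26 gave a p of 0.1, the smallest that 3 against 3 libraries can give.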

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

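The tests of dilution, normalization, hepatocyte RNA, exchange and a wrong label were chosen after the results they bear on were seen, and the counts over other splits were planned before any split was computed.

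A test of the difference between the effect of polyIC with and without the antibody picked out the results that follow. Orm2 had an interaction of -2.35 on the log2 scale. The small RNA genes Mir5107 and Mir760 had fitted values of -6.27 and 3.04, which depend on the pseudocount, since they were listed at 0 in all groups but polyIC and control, respectively. Among the lists, NK cell markers had a median of -1.52 (adjusted p = 0.0962 with an estimated correlation), cytotoxic effector genes -0.88 and monocyte markers -0.53 (adjusted p = 0.623 with an estimated correlation for both). Hepatocyte markers had -1.30 (adjusted p = 0.623 with an estimated correlation). Kupffer cell markers had -0.99, cell cycle genes -0.61, ribosomal protein genes -0.35, neutrophil markers -0.31 and interferon-stimulated genes -0.30 (adjusted p = 0.705 with an estimated correlation for each). Checkpoint genes had -0.34 and endothelial markers -0.23 (adjusted p = 0.723 with an estimated correlation for both). Leaving out 1 library moved 10 of these 11 medians by over 1.5 times, all but that of NK cell markers (-1.87 to -1.31). The medians ranged from -1.26 to -0.37 for cytotoxic, -1.84 to -0.75 for hepatocyte, -1.49 to -0.34 for Kupffer and -1.035 to -0.36 for cell cycle genes. They changed sign for checkpoint genes without antiPDL1 replicate 0 (0.026), for neutrophil markers without polyIC replicate 1 or antiPDL1 replicate 1 (0.013 and 0.12), and for endothelial markers without control replicate 2 (0.063). Without control replicate 2 and antiPDL1 replicate 2 together, the Kupffer and endothelial medians changed sign (0.11 and 0.29) and the hepatocyte median was -0.30.

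NK cell markers were higher with polyIC alone (adjusted p = 0.276 with an estimated correlation) and did not pass with the combination. Dilution by other immune cells predicts a like fall of the types that did not grow. Between the combination and polyIC the NK genes not shared with the cytotoxic list had a median of -1.68 (quartiles -1.95 and -1.09). The cytotoxic list and monocytes stood at 0.19 and 0.08, with a smaller gap of 1.76, but B cell markers (-1.22), Kupffer markers (-2.05) and plasmacytoid markers (-0.79) fell too (adjusted p = 0.314 for each with an estimated correlation), with quartiles that overlap those of the NK genes, so dilution stays open for this fall. In the interaction, B cell and plasmacytoid markers had medians of 0.01 (0.0128) and 0.088 (quartiles -0.14 and 0.19, and -0.13 and 0.18), while the NK genes had -1.52 (-2.10 and -1.16). That gap of 1.53 argues against 1 dilution common to all these types as the whole cause of the interaction. Kupffer and hepatocyte markers did go with the NK genes there (-0.99 and -1.30, adjusted p = 0.705 and 0.623 with an estimated correlation), although without control replicate 2 and antiPDL1 replicate 2 they had 0.11 and -0.30 against -1.80 for the NK list, and a dilution of part of the cell types stays open. The authors' normalization is argued against by the rescaled values, of which the interaction median nearest to 0 was -1.56. Fewer NK cells, or NK cells with less of these transcripts, may both give this pattern, and neither was tested. The interaction itself did not pass with an estimated correlation, so the pattern stays a hypothesis.

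In the combination T cell genes were higher while hepatocyte, Kupffer and B cell genes were lower (adjusted p = 0.331 for T cell and 0.278 for the other lists with an estimated correlation). A smaller share of hepatocyte RNA would raise every immune cell list alike, yet the B cell median lay below the T cell median by -4.22, with B cell quartiles of -2.36 and -1.95 and T cell quartiles of 0.95 and 2.31. With the hepatocyte mean as a covariate the cytotoxic median fell to 1.16 from 2.55, a fall of the size that had been written down as the mark of carried-over RNA, while the median SE of its genes went from 0.412 to 0.634 and the list still passed at the preset correlation (adjusted p = 6.35e-09) but not with an estimated one (adjusted p = 0.263). Since 76.8% of the variance of that covariate lies between the groups, carried-over RNA and treatment cannot be told apart for these genes, and this reading of the test was settled after its value was seen. A change in the make-up of the liver's immune cells through treatment may also account for the pattern and was not tested.

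Few genes passed in antiPDL1 against control, 25, while 3285 passed without control replicate 2 and antiPDL1 replicate 2. On 1588 genes that separate the other controls (position 0) from the other antiPDL1 libraries (position 1), control replicate 2 lay at 0.568 (quartiles 0.130 and 0.877) and antiPDL1 replicate 2 at 0.304 (0.0884 and 0.510), the sides on which an exchange of the pair would put them, and a requirement that the quartiles also clear the midpoint was added only after these values were seen. These genes were chosen from the other libraries, which by itself can draw a left-out library toward the middle. The polyIC libraries lay at 0.594 to 0.754 on them, so the position of control replicate 2 does not point to antiPDL1 in particular. Against an exchange, the cell cycle mean of control replicate 2 was 3.15, near the other controls (3.34 and 3.43) and not the other antiPDL1 libraries (4.67 and 4.85), its B cell mean was 6.05 against 3.54 and 4.19, and its Sprr1a value was 34.4 FPKM against 1.16 in antiPDL1 replicate 2. Other values go with an exchange: antiPDL1 replicate 2 had a cell cycle mean of 3.47 and a B cell mean of 4.79 (other controls 4.90 and 5.10), and its hepatocyte and Kupffer means were 5.80 and 8.82. Control replicate 2 had hepatocyte and Kupffer means of 5.003 and 7.18, against 6.70 and 6.20, and 9.16 and 9.17, in the other controls and 4.71 and 3.77, and 6.78 and 8.10, in the other antiPDL1 libraries. A wrong label on an untreated library was tested on 630 genes lower with polyIC and the combination, where antiPDL1 replicate 2 lay at 0.382 (quartiles 0.240 and 0.518), between the bounds set for either answer. On the same genes control replicate 2 lay at 0.742 (0.567 and 0.887), beyond antiPDL1 replicate 1 at 0.625 and beside the polyIC libraries (0.729 to 0.883). The Kupffer mean of control replicate 2, 7.18, also lay among those of the polyIC libraries (6.82 to 7.49). Its cell cycle, B cell and NK means of 3.15, 6.05 and 5.47 argue against a polyIC library under this label. The polyIC libraries had 4.19 to 4.785, 3.96 to 4.67 and 6.34 to 6.89. With lists that go both ways, a wrong label of control replicate 2 stays undecided. The library antiPDL1 replicate 0 correlated more with the combination (0.960) than with its own group (0.940), and whether its label is right was not tested. An exchange, a wrong label and a mouse that responded little to the antibody all stay open.

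Counts were repeated over the 10 ways to split the 6 libraries of each comparison, too few for a share under 0.05. For called genes, 1 split, the real one, reached 437 in polyIC against control (highest other 4), 1 reached 3527 in the combination against control (highest other 2), 1 reached 148 against polyIC (highest other 2) and 1 reached 15 against antiPDL1 (highest other 1). In the other splits a library of each group changes sides, so a real group difference enters the spread within groups and lowers the count. The size of these gaps is therefore no measure of chance. In antiPDL1 against control 2 splits reached 25, and the other, which exchanges control replicate 2 and antiPDL1 replicate 2, called 1377, which points to a structure of these samples other than the groups. For called lists the real and highest other values were 16 and 16 with polyIC, 17 and 19 with antiPDL1, 19 and 19 with the combination and 17 and 17 against polyIC, with 2 splits as large in each, and 18 and 17 against antiPDL1, with 1. For the interaction 100 splits were counted, the real one and random shuffles of the labels of all 12 libraries. With the real one included, 6 gave at least its 3 genes (highest other 1104) and 75 at least its 11 lists (highest other 21). Such shuffles mix libraries of all 4 groups, so effects of the treatments themselves enter the shuffled contrast. The counts are therefore no measure of chance for the interaction, chance is not excluded for genes or lists, and the source of the high counts stays open.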

How the results depend on the processing

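The hepatocyte covariate, the kept failed estimates, the left-out small RNA genes and the joint removal of control replicate 2 and antiPDL1 replicate 2 were chosen after the data were seen, and all other alternatives before. Of 4970 repeats of named gene results, 4107 kept their side of the threshold, 790 lost the call and 69 gained one. The other 4 reversed, that is, changed sign with a call in the main or the repeated fit. The 4107 include changes of sign where neither fit called the gene, such as Alb with polyIC (-0.79 to 0.05 with 1 library out). All 4 reversals of a call came with the hepatocyte covariate: Isg20 -0.11, Ms4a4c -0.0202 and Alb 0.16 in the combination against control, and Apoc3 0.01 (0.0065) against polyIC. Alb and Apoc3 belong to the list whose mean is the covariate, so that fit takes up their change by construction and is no test of them. Of 173 named calls 7 held under each alternative that tested them: Car2, Gzma, Krt18, Krt8, Mgl2 and Sprr1a with polyIC, and Mir5107 for the interaction. This count rests much on the hepatocyte covariate, which left 2 called genes in the combination against control and 677 with polyIC. That covariate cannot be told apart from treatment. With 1 library out, 62 of 81 named calls held in every run in the combination against control, and 6 of 44 with polyIC. Krt8 and Mgl2 were not tested at a mean FPKM of at least 5, nor Sprr1a without control replicate 2 and antiPDL1 replicate 2. Mir5107 was not tested with small RNA genes left out or without any 1 of the polyIC replicates 0, 1 and 2, and so was not called there. Its zeros in whole groups match those read as failed estimates in other genes. The relative depth, lowest in polyIC and antiPDL1, limits what low genes can show there, and no read counts were at hand to compute a floor. Except where fewer genes or libraries entered a fit, the cause of each change was not tested.

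Comparisons are given in the order polyIC against control, antiPDL1 against control, combination against control, combination against polyIC, combination against antiPDL1, and interaction. With an estimated correlation camera called 0, 0, 0, 0, 0 and 0 lists, with 3, 2, 1, 4, 2 and 1 at an unadjusted p under 0.05, and fry called 7, 1, 17, 4, 0 and 0. Leaving out 1 library moved the called genes from 40 to 1844, 0 to 2089, 1681 to 4442, 0 to 536, 0 to 329 and 0 to 5, and the called lists from 15 to 19, 16 to 20, 17 to 19, 16 to 18, 15 to 20 and 10 to 13. A left-out library leaves its group with 2, and no group fell to 1.

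A mean FPKM of at least 5 gave 212, 5, 1963, 77, 6 and 1 genes, from fewer genes tested. Array quality weights gave 3439, 2585, 6883, 3654, 818 and 13. Without control replicate 2 and antiPDL1 replicate 2 the counts were 2801, 3285, 5078, 1116, 88 and 5. With the hepatocyte covariate they were 677, 1, 2, 1 and 3 in the first 5 comparisons, and 11 lists were called in the combination against polyIC. Of the lists called there in the main fit 12 were lost, and 6 others were gained. In the combination against control the covariate lost 5 called lists, gained 1 and turned 1 to a call in the opposite direction. The hepatocyte list supplies the covariate, so its own result in these fits is no test of that list. No filter gave 139 in antiPDL1 against control, 26 against polyIC and 31 against antiPDL1 in the combination. A pseudocount of 0.1 gave 344, quantile normalization 6, median-of-ratios rescaling 20 and a replicate block 7 in the combination against polyIC. Quantile normalization gave 783 in polyIC against control. A replicate block gave 1 in the combination against antiPDL1. Fits of only the groups compared gave 2 in antiPDL1 against control, 1344 against polyIC and 1 against antiPDL1 in the combination. The 2 genes and the 1 gene included 0 of the genes called in the main fit. Keeping failed estimates gave 40 in antiPDL1 against control and 12 for the interaction. Without small RNA genes the counts were 248 against polyIC, 53 against antiPDL1 and 0 for the interaction.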

Other observations

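The genes in this part were picked after their values were seen, and each that passed the expression filter was tested in the limma fit over all genes. The calls are of single genes, and no set of them was tested. Gcg, the proglucagon gene, was 0.708 ± 1.02 FPKM in control, 5.72 ± 2.09 with polyIC, 2.22 ± 2.69 with antiPDL1 and 73.5 ± 36.2 with the combination (SD, n = 3 each), a rise of 5.50 on the log2 scale in the combination against control (adjusted p = 0.000648, higher in 3 of 3 libraries). It did not pass with polyIC or antiPDL1 alone (adjusted p = 0.0668 and 0.486). Glp1r, which encodes the receptor of a proglucagon product, was 0.160 ± 0.0126, 6.65 ± 2.59, 1.33 ± 2.03 and 4.25 ± 1.96 FPKM in the same order, with log2 changes from control of 2.66 with polyIC, 0.67 with antiPDL1 and 2.10 with the combination (adjusted p = 0.0192, 0.494 and 0.0115). Calcb, a calcitonin gene-related peptide gene, was 0.144 ± 0.121, 15.98 ± 12.5, 0.331 ± 0.332 and 9.45 ± 4.48, with changes of 3.49, 0.19 and 3.12 (adjusted p = 0.0120, 0.873 and 0.00409). Calca, the sister gene of Calcb, was 0.124 ± 0.0869, 2.82 ± 2.95, 0.184 ± 0.256 and 1.61 ± 1.53, and did not pass with polyIC (log2 1.504, adjusted p = 0.0977) or the combination (1.07, adjusted p = 0.106). The calls of Gcg, Glp1r and Calcb in the combination against control held in all 12 runs with 1 library out. With polyIC, Glp1r missed the threshold without control replicates 0 and 1 or polyIC replicates 0 and 1 (adjusted p = 0.0723, 0.08001, 0.0984 and 0.0707), and Calcb without control replicate 1 or polyIC replicates 0 and 2 (0.0579, 0.0551 and 0.0509). Dpp4, next to Gcg in the genome and the gene of an enzyme that degrades its products, stood at 25.8 ± 4.07 FPKM in the combination and 30.3 ± 5.19 in control (adjusted p = 0.395).

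In the combination against control, Cd207, Ccl17 and Il12b fell, with log2 changes of -4.31, -3.63 and -1.495 (adjusted p = 0.000776, 0.000435 and 0.00694, each in all 12 runs with 1 library out). With polyIC they had changes of -2.87, -2.68 and -1.49 (adjusted p = 0.0125, 0.00359 and 0.0297). There Ccl17 passed in all 12 runs, Cd207 missed the threshold without control replicates 0 and 1 or polyIC replicate 0 (adjusted p = 0.0563, 0.0579 and 0.0599), and Il12b without control replicate 1 or polyIC replicates 0 and 2 (0.116, 0.143 and 0.101). Xcr1 and Clec9a had changes of -0.10 and -0.45 in the combination (adjusted p = 0.855 and 0.320), and no difference between these genes was tested. Elane and Mpo rose with polyIC by 2.07 and 2.00 (adjusted p = 0.00271 and 0.0078), and both failed the expression filter without any 1 of the polyIC replicates 0, 1 and 2. Prtn3 rose by 1.96 (adjusted p = 0.0220) and missed the threshold without control replicates 0 and 1 or polyIC replicates 0, 1 and 2 (adjusted p = 0.0876, 0.0892, 0.067, 0.0763 and 0.0757), and Ctsg failed the expression filter. Tgfbi, a matrix protein gene induced by TGF-beta, rose from 120 ± 31.2 to 441 ± 122 FPKM in the combination (log2 1.87, adjusted p = 0.00538, in all 12 runs).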
